A study of Mus musculus with 8 samples.

How the data were processed

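H2AK119ub, histone H2A carrying a single ubiquitin on a lysine near its end, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in basal epidermal progenitors of newborn mice at postnatal day 0. Per the labels' protocols, cells were sorted for EpCAM, Sca1 and high α6-integrin, and each immunoprecipitation used a fixed number of sorted cells. The series held 8 libraries of 3 genotypes: 5 H2AK119ub libraries (2 control, 2 Eed cKO and 1 Ring1a/b 2KO) and 3 inputs, 1 per genotype. Groups were taken from the labels. The labels do not say which animals or litters the libraries came from, and the sex of the mice is not given.

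The deposited data were a pair of peak lists, 1 for control and 1 for Eed cKO. Each held chromosome, start and end of every peak in mm10, per the file headers and the submitters' processing notes, with no score, height, fold or p-value. Bowtie2 2.3.3.1 and SAMtools 1.9 are named in the submitters' processing notes. The peak caller, its threshold, the use of the inputs and the way the 2 libraries of a genotype were joined are not given in the sources used here. The Ring1a/b 2KO library and the inputs as such were not analysed here. Read depth is unknown from peak positions, so a list with fewer peaks can reflect less mark, fewer reads or a different call threshold. With 1 list per genotype there was no replicate error. Tests therefore compared the lists, not the conditions, and neither peaks nor genes are replicates.

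Peaks were annotated with RefSeq coordinates of 21887 protein-coding genes of GRCm38, the assembly also called mm10. The gene table carried no strand. The window planned at the 5′ end of each gene was therefore replaced by 2000 bp on either side of both ends of the gene span, and a gene with a peak overlapping such a window by at least 1 bp was called marked. The alternative planned for gene bodies became the gene span with 2000 bp on both sides. No genome sequence and no exon annotation were used, so CpG content was not computed, the CpG-dense background was not run, and peaks were described as lying at gene ends, inside gene spans or outside them. Positions are given from 1, as a genome browser shows them.

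Overlap between the lists required 1 bp (bedtools 2.31.1) and was set beside 1000 random placements of the peaks within their chromosomes. Median widths were compared by two-sided permutation tests with 100000 resamples. Gene lists were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists at a threshold of 0.05. For enrichment the background was all protein-coding genes. For retention, the share of control-marked genes also marked in Eed cKO, it was all other control-marked genes. The 21 lists were fixed before the data were examined, as were the tests and most alternatives. Some genes are members of several lists. All members of the lists were found in the gene table except 1 of the 21 leukocyte genes. Shares carry 95% Wilson intervals, which cover counting error only. Stratified odds ratios are Mantel-Haenszel estimates over 10 strata. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

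Genes were named by a rule set in advance: a fixed set of Polycomb, lineage and reference genes, the 10 genes with the widest peaks among those marked in both lists, in control alone and in Eed cKO alone, and up to 2 genes per list marked in both lists and up to 2 in control alone. Genes outside this rule were chosen after their values were seen. They are the members listed for small groups and for genes marked in Eed cKO alone. Some genes that the rule names are not reported here.

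The alternatives were a stricter list (the wider peaks of each list, since no score was given), a control list trimmed to as many peaks as the Eed cKO list, merging of peaks within 1000 bp, other overlap rules, other gene windows, autosomes alone and control-marked genes with the wider peaks. The functions were tested on simulated data. All of 1865 planted overlapping peaks were recovered (100%), against 1.05% of 2756 others. Of 100 random sets of marked genes, 1 gave any list call, and 97 of 100 planted gene lists were called. The planted lists were larger than all tested lists but the Zfp and olfactory receptor lists. How often smaller lists would be called was therefore not tested. Random sets also do not reproduce peaks shared by neighbouring genes, so the rate of false calls under such sharing was not tested. In 96 of 100 simulations in which the decile of control peak width alone set the overlap of 2550 genes, the stratified interval held 1. Width had no effect within a decile there, so width differences left inside a stratum were not tested.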

Results

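H2AK119ub, the mark placed by Polycomb repressive complex 1 (PRC1), was mapped in epidermal progenitors of control mice and of mice with a conditional knockout (cKO) of Eed, a core subunit of Polycomb repressive complex 2 (PRC2), which methylates H3K27. Each genotype contributed 2 H2AK119ub libraries and 1 peak list. The comparison addressed which H2AK119ub regions were still called in Eed cKO. No H2AK119ub peak lay at the Eed gene in either list, and peak positions cannot show whether the gene was deleted. Peaks carried no score, so widths and positions are the measured quantities, and they have no replicate error.

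The control list held 4621 H2AK119ub peaks covering 29.0 Mb, and the Eed cKO list held 2541 peaks covering 16.6 Mb. The Eed cKO list thus had 55.0% as many peaks and 57.3% as much covered sequence. Eed cKO peaks overlapped 1751 control peaks, or 37.9% (36.5 to 39.3), among them peaks at the Hox clusters, Sox2, Atoh1 and Shh. The remaining 2870 control peaks, including the peak over Cdkn2a and Cdkn2b, met no Eed cKO peak. In the other direction, 1781 Eed cKO peaks (70.1%, 68.3 to 71.8) overlapped a control peak and 760 did not. Randomly placed peaks overlapped in 1.43% of control peaks on average and in at most 2.14%, giving a permutation p = 0.001, the smallest that 1000 placements allow. Read depth behind either list was unknown, so the difference in peak number cannot be assigned to the mark itself.

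Control peaks that met an Eed cKO peak were wider than those that did not, with medians of 5911 and 3727.5 bp (permutation p = 1e-05, the smallest that 100000 resamples can give). The share overlapped was 25.0% (22.3 to 27.9) in the narrowest of 5 equal width classes of control peaks, from 543 to 2274 bp. It was 62.1% (58.9 to 65.2) in the widest class, from 8027 to 136783 bp. Eed cKO peaks were wider than control peaks over the whole lists, with medians of 5169 and 4327 bp (permutation p = 1e-05). This direction turned when the control list was trimmed to its widest peaks, which raises the control median by construction. In the 1470 pairs where 1 control peak met 1 Eed cKO peak, the medians were 5.72 kb in control and 5.78 kb in Eed cKO. Eed cKO peaks without a control peak had a median width of 3606 bp, against 6121 bp for those with one.

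**Figure D1:**
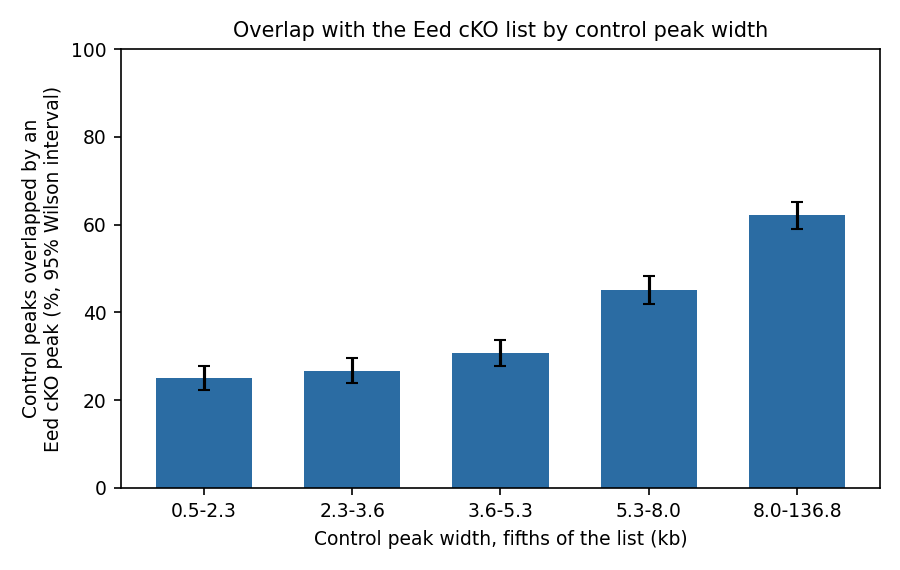
Share of control H2AK119ub peaks (%) overlapped by an Eed cKO peak, for 5 equal classes of the control list by peak width (kb); lines are 95% Wilson intervals, which cover counting error only. The share is 25.0% in the narrowest and 62.1% in the widest class.

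At the level of genes, 2550 of 21887 protein-coding genes (11.7%) were marked in control and 1620 (7.40%) in Eed cKO. Both lists marked 1249 genes, including Sox2, Atoh1, Isl1, Shh and many Hox genes. Control alone marked 1301, including Cdkn2a, Cdkn2b and Gata6, and Eed cKO alone marked 371, including Irx2, Wnt4 and Wnt7b. Of these 371 genes, 61 (16.4%) lay under an Eed cKO peak that overlapped a control peak away from the ends of the gene, as at Fgfr3 and Foxn1. Likewise 80 of the 1301 genes (6.15%) lay at a control peak that overlapped an Eed cKO peak elsewhere. Of the control-marked genes, 49.0% (47.0 to 50.9) were also marked in Eed cKO. Of the Eed cKO-marked genes, 77.1% (75.0 to 79.1) were also marked in control. Independent lists of these sizes would share 189 genes, and the odds ratio of the overlap was 49.1 by Fisher's exact test.

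Developmental transcription factor genes made up the most heavily marked groups in control cells. Homeobox genes outside the Hox clusters were marked in 85 of 92 cases (92.4%, 85.1 to 96.3), neuronal factors in 30 of 34, mesodermal and endodermal factors in 32 of 37 and Hox genes in 32 of 39. Paired box, SRY box, forkhead, T-box and GATA factors were marked in 60 of 91 cases. The same groups were marked above background in Eed cKO, with 69 of 92 homeobox genes, 22 of 34 neuronal, 24 of 37 mesodermal and endodermal, 26 of 39 Hox and 41 of 91 paired box to GATA genes. The highest adjusted p among these 5 lists was 2.6e-23 in control and 9.4e-17 in Eed cKO (Fisher's exact test, Benjamini-Hochberg over 21 lists). Genes share peaks, most of all in the Hox clusters, where 12 control peaks marked the 32 genes, so these p-values are too small there.

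The widest H2AK119ub domain in control spanned the Hoxd cluster, whose genes pattern the body axis and limbs. It ran for 136.8 kb on chromosome 2 (74639331 to 74776113) over Evx2 and Hoxd1 to Hoxd13. In Eed cKO, 5 separate peaks covered 41.6% of it. The widest, 22.7 kb, lay at Evx2 and Hoxd13, an 8.82 kb peak lay at Hoxd11 and Hoxd12, and Hoxd8, Hoxd9 and Hoxd10 had no Eed cKO peak at either end. The Hoxc domain, 115.1 kb on chromosome 15 over Hoxc8 to Hoxc13, was covered to 38.4% by 4 Eed cKO peaks. The domain at Evx1 and Hoxa9 to Hoxa13, 109.4 kb on chromosome 6, was covered to 51.7%. Among other lineage factors marked in both lists, Pax3 had a 61.7 kb control peak, of which 2 Eed cKO peaks covered 31.3%. At Hand2, a heart and limb factor, 3 Eed cKO peaks covered 31.3% of a 56.7 kb control peak. At Pax2, a kidney factor, 2 covered 51.9% of 50.6 kb, and at Gata4 2 covered 76.3% of 44.9 kb. The control peaks at Vax2 (40.2 kb), Gata6 (28.7 kb), Lmx1a (19.6 kb) and Tcf21 (16.8 kb) were not covered by any Eed cKO peak.

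**Figure D2:**
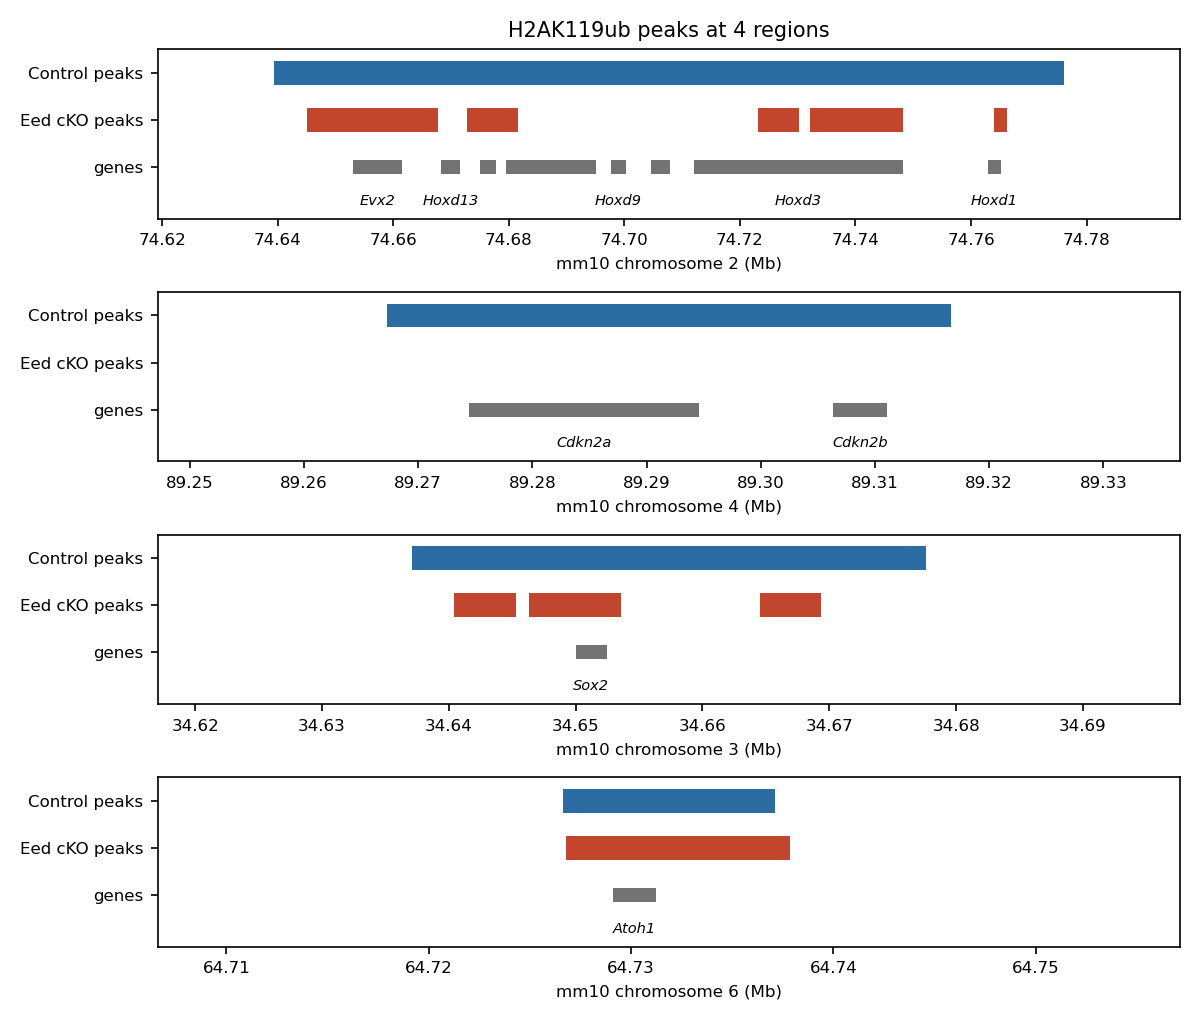
H2AK119ub peaks of the control and Eed cKO lists and protein-coding gene spans at 4 regions of mm10, drawn to scale within each region (Mb), with selected genes named. A single control peak spans the Hoxd cluster and 5 Eed cKO peaks lie in it; Cdkn2a and Cdkn2b have a control peak alone, Sox2 has 3 Eed cKO peaks within its control peak, and the Atoh1 peaks nearly coincide.

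Retention differed between groups. Of the control-marked homeobox genes outside the Hox clusters, 67 of 85 (78.8%, 69.0 to 86.2) were also marked in Eed cKO, against 48.0% of other control-marked genes (adjusted p = 2.6e-07, Fisher's exact test). The same share was 23 of 32 for Hox genes, 22 of 30 for neuronal factors, 23 of 32 for mesodermal and endodermal factors and 39 of 60 for paired box to GATA factors, each at adjusted p = 0.049 by Fisher's exact test. With each control peak counted once, an alternative added after the data were seen, the Hox call was lost on fewer units (9 of 12 peaks, adjusted p = 0.24, Fisher's exact test). Its odds ratio was then 3.22, against 2.61 per gene. Per peak, any overlap with an Eed cKO peak counted, not only a peak at a gene end, so these measures differ. Of the 19 lists that could be tested, these 5 were higher and 0 lower. The 5 lists share members, so their calls are not independent. Pax3 and Pax6, for example, are in both the neuronal and the paired box to GATA lists. Foxa1 and Gata4 are in both the mesodermal and endodermal and the paired box to GATA lists. The 5 lists were joined after these calls were seen, so no p is given for the joined count of 153 of 211 genes, against 1096 of 2339 other genes. Under 5 of 8 other settings of lists, windows and backgrounds the homeobox list alone stayed past the threshold. The neuronal call was also lost with a window of 5000 bp (adjusted p = 0.06) and with the gene span (adjusted p = 0.053), by Fisher's exact test. Within strata of control peak width, a comparison added after the data were seen, no list passed it.

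**Figure D3:**
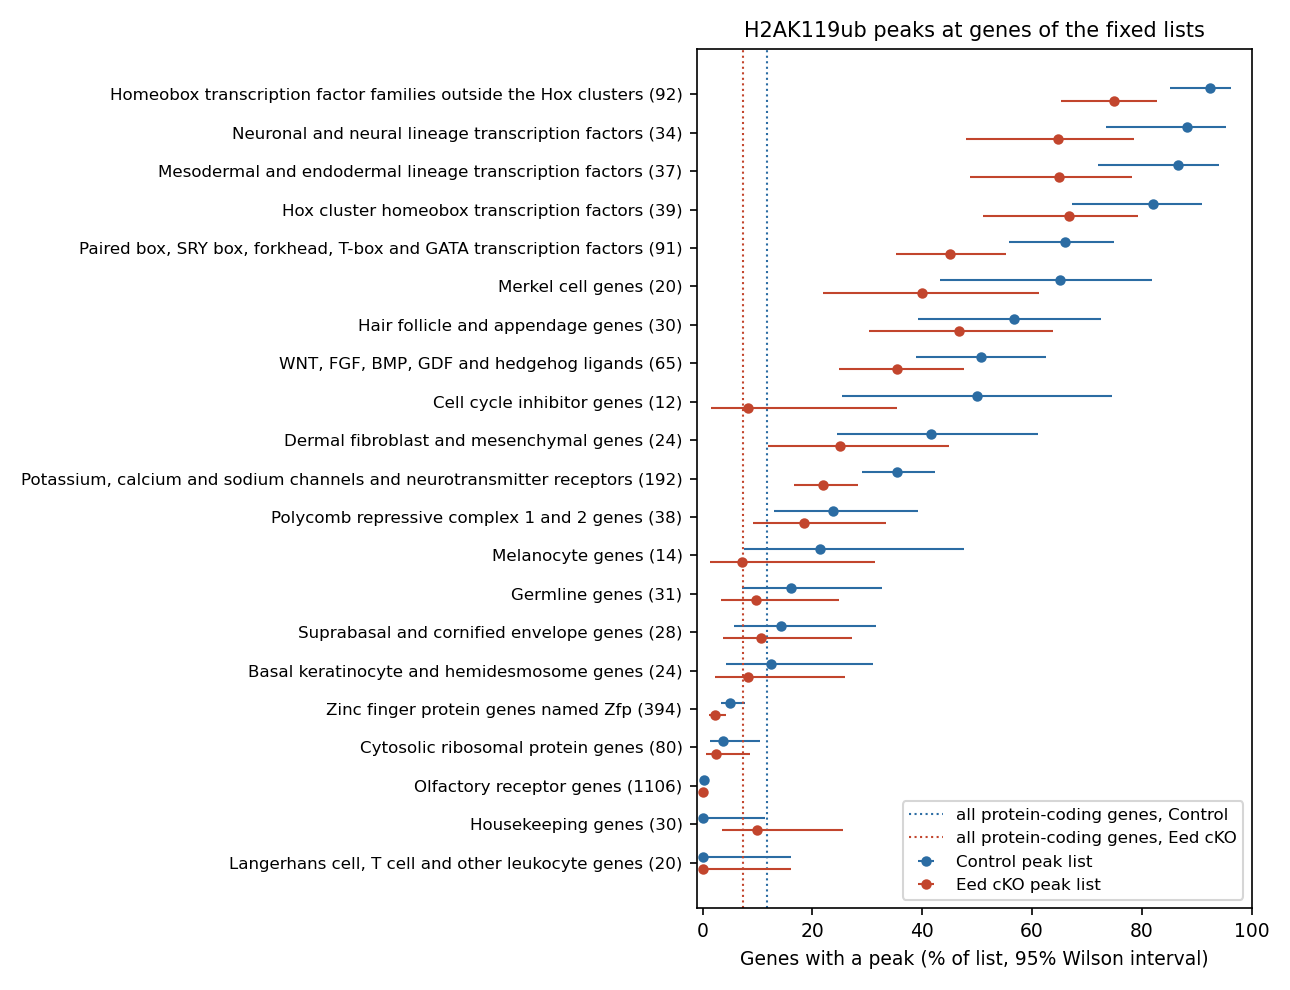
Share of genes in each list (%, list size in brackets) with an H2AK119ub peak within 2000 bp of a gene end in the control and Eed cKO peak lists; points are shares, lines 95% Wilson intervals, and dotted lines the shares of all protein-coding genes. Homeobox genes outside the Hox clusters lie highest, at 92.4% in control, and olfactory receptor genes are near 0.

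Genes of Merkel cells, the touch receptors that arise from the epidermis, were marked in control in 13 of 20 cases (65.0%, 43.3 to 81.9; adjusted p = 5.2e-08, Fisher's exact test). In Eed cKO 8 of 20 were marked (adjusted p = 9.5e-05, Fisher's exact test). All 8 were also marked in control: Sox2, Atoh1, Isl1, Gfi1, Insm1, Krt8, Krt18 and Tubb3. Sox2, an early Merkel factor, lay in a 40.5 kb control peak on chromosome 3 (34637083 to 34677631), of which 3 Eed cKO peaks covered 41.8%. The peak of Atoh1, the factor required for Merkel cell formation, was 10.5 kb in control and 11.1 kb in Eed cKO. At Isl1 a 32.9 kb control peak was matched by a 3.1 kb Eed cKO peak. Prox1 (12.7 kb), Pou4f3 (9.53 kb), Ncam1, Cck and Dnajc6 were marked in control alone. Sox2, Isl1 and Pou4f3 are also in the developmental factor lists, so the Merkel list is not independent of them. Retention of the list, 8 of 13, did not pass the threshold against other control-marked genes (adjusted p = 0.87, Fisher's exact test).

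Hair follicle and appendage genes were marked in 17 of 30 cases in control (56.7%, 39.2 to 72.6; adjusted p = 8e-09) and in 14 of 30 in Eed cKO (adjusted p = 1.5e-08), by Fisher's exact test. Marked members such as Hoxc13, Lhx2, Sox9, Shh and Wnt10a are also in the developmental factor or ligand lists, so this is not a separate group. Shh, the hedgehog ligand of the hair bud, had a 17.9 kb control peak on chromosome 5, of which 87.8% was covered in Eed cKO. Lhx2, a hair follicle stem cell factor, lay in a 48.4 kb control peak covered to 76.9%. Wnt5a (17.2 kb) and Gata3 (16.5 kb) were marked in control alone, as were Msx2 and Fgf5. The nearest Eed cKO peak lay 45.0 kb from Wnt5a, while at Gata3 one lay inside the gene span, away from its ends and from the control peak. Of the control-marked members 13 of 17 were also marked in Eed cKO, which did not pass the threshold (adjusted p = 0.087, Fisher's exact test). It passed with the gene span as the window (adjusted p = 0.037, Fisher's exact test) and with each control peak counted once (adjusted p = 0.038, Fisher's exact test). WNT, FGF, BMP, GDF and hedgehog ligands were marked in 33 of 65 cases in control and 23 of 65 in Eed cKO. Channel and neurotransmitter receptor genes were marked in 68 of 192 and 42 of 192. Both lists were above background in both genotypes, with a highest adjusted p of 3.9e-10.

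Cell cycle inhibitor genes, a list that also holds Ccnd1, were marked in 6 of 12 cases in control (adjusted p = 0.002, Fisher's exact test) and in 1 of 12 in Eed cKO (adjusted p = 0.67). Cdkn2a and Cdkn2b, which encode the INK4 and ARF inhibitors, lay under a single 49.4 kb control peak on chromosome 4 (89267246 to 89316678). No Eed cKO peak touched it, and the nearest one lay 1519 kb from Cdkn2a. Cdkn1a, Cdkn2c and Ccnd1 were also marked in control alone. Cdkn1c had a 9.01 kb control peak that lay inside a 14.7 kb Eed cKO peak. Retention of the list, 1 of 6, did not pass the threshold against other control-marked genes (adjusted p = 0.59, Fisher's exact test).

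Basal keratinocyte genes were marked in 3 of 24 cases in control (12.5%) and 2 of 24 in Eed cKO (8.33%), and suprabasal genes in 4 of 28 (14.3%) and 3 of 28 (10.7%). Other genes were marked in 11.6% of cases in control and 7.40% in Eed cKO, and no difference from them passed the threshold (lowest adjusted p = 0.58, Fisher's exact test). Krt5, Krt14 and Trp63, which define basal keratinocytes, had no peak in either list. Krt15, a basal keratin, was marked in both lists by peaks shared with Krt19, 10.8 kb in control and 31.2 kb in Eed cKO. Krt1, a keratin of differentiating cells, had peaks of 3.66 and 6.58 kb. Krt10, its partner, had a 2.19 kb peak in control alone. Dst, Tfap2c, Krt2 and Notch3 were marked in control alone, with an Eed cKO peak inside the span of Tfap2c away from its ends, and Jag2, Grhl3 and Tgm5 in Eed cKO alone. The Eed cKO peak at Grhl3 overlapped a control peak away from the ends of that gene.

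Among lists for other cell types, 0 of 20 leukocyte genes were marked in either list, which allows a share of up to 16.1%. Dermal fibroblast and mesenchymal genes were marked in 10 of 24 cases in control (adjusted p = 0.00033) and 6 of 24 in Eed cKO (adjusted p = 0.012), by Fisher's exact test. En1 (31.9 and 25.6 kb) and Twist1 (30.0 and 1.67 kb) were marked in both, and Zeb2 (16.7 kb) and Pdgfra (14.7 kb) in control alone. The marked members En1, Prrx1, Prrx2, Twist1 and Twist2 are also in the developmental factor lists, so this is not a separate group. Melanocyte genes were marked in 3 of 14 and 1 of 14 cases and germline genes in 5 of 31 and 3 of 31, without passing the threshold. Pax3 was the melanocyte gene in both lists, and Sox10 and Kit were in control alone. Dmrt1 and Smc1b were the germline genes in both.

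Genes of the Polycomb complexes were marked in 9 of 38 cases in control (adjusted p = 0.051) and in 7 of 38 in Eed cKO (adjusted p = 0.032, Fisher's exact test). The Eed cKO call was lost with a window of 1000 bp. The control list passed with the wider peaks (adjusted p = 0.039), a window of 5000 bp (0.0017), the gene span (0.00013) and autosomes alone (0.042), by Fisher's exact test. Cbx8 had peaks of 14.8 and 14.3 kb and Epop of 9.53 and 9.30 kb. Cbx6 and Phc2 were also marked in both lists. Pcgf1, Pcgf2, Bmi1 and L3mbtl2 were marked in control alone, and Cbx2 and Ring1 in Eed cKO alone. Eed cKO peaks away from the ends of these genes still covered 83.1% of the control peak at L3mbtl2 and 47.9% of that at Pcgf1. The L3mbtl2 control peak was shared with Chadl, and the Pcgf1 control peak with Tlx2 and Dqx1. In turn, the Eed cKO peak at Cbx2 overlapped a control peak away from the ends of Cbx2. The 5.09 kb peak at Ring1, which encodes a PRC1 ubiquitin ligase, also lay at Rxrb, Slc39a7 and H2-Ke6. Ezh2, Suz12 and Rnf2 had no peak in either list.

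Comparison groups lay at or below background. Olfactory receptor genes were marked in 2 of 1106 cases in control and 0 of 1106 in Eed cKO, which allows up to 0.346%. Zfp genes were marked in 20 of 394 and 9 of 394 cases. Both lists were lower than other genes in both genotypes (highest adjusted p = 3.1e-05, Fisher's exact test). Ribosomal protein genes were marked in 3 of 80 cases in control (adjusted p = 0.034) and 2 of 80 in Eed cKO (adjusted p = 0.19, Fisher's exact test). The control call was lost with the wider peaks, the trimmed list and a window of 5000 bp. Housekeeping genes were marked in 0 of 30 cases in control, which allows up to 11.4%, and in 3 of 30 in Eed cKO, namely Actb (4.42 kb), Gpi1 and Tubb5. Neither count passed the threshold (adjusted p = 0.056 and 0.58, Fisher's exact test), but the control count passed as lower with a window of 5000 bp (adjusted p = 0.039) and with the gene span (adjusted p = 0.037). Gapdh had no peak in either list.

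Control peaks that met an Eed cKO peak lay at gene ends in 59.4% of cases, against 42.7% of the other control peaks (odds ratio 1.96, Fisher's exact p = 2.5e-28). The overlapped peaks were also wider, with medians of 5911 and 3727.5 bp, and a wider peak reaches a gene end more easily. These sets were not matched for width, so location and width were not told apart. Over the whole lists 49.0% of control and 53.3% of Eed cKO peaks lay at gene ends. Of the Eed cKO peaks without a control peak, 37.9% did.

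The X chromosome had the lowest share of overlapped control peaks, 10 of 61 (16.4%, 9.16 to 27.6) against 38.2% on other chromosomes (adjusted p = 0.0022, Fisher's exact test over 20 chromosomes). Tsc22d3, a glucocorticoid-induced gene on it, had a 55.3 kb control peak that was covered to 48.6%. Chromosomes 3 (24.6%, adjusted p = 0.0014) and 18 (26.0%, adjusted p = 0.031) were also lower, and chromosome 8 was higher (48.5%, adjusted p = 0.0022), all by Fisher's exact test. With 50% of a peak covered, 5 chromosomes passed in place of 4, and the share on X was 6.56% (adjusted p = 3e-05, Fisher's exact test). Counting peaks within 1000 bp as shared it was 18.0% (adjusted p = 0.0053, Fisher's exact test). Median control peak width was 2561 bp on X and 4346 bp on autosomes. The odds ratio for X was 0.332 (0.161 to 0.687) within strata of control peak width and 0.382 (0.195 to 0.750) within strata of gene density. The sex of the mice behind either list is not given. A difference in sex between the lists could not be checked, so the low share on X cannot be assigned to genotype.

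Where 1 control peak met 1 Eed cKO peak, widths were compared directly, a comparison added after the data were seen. At developmental transcription factor genes of the 5 joined lists the Eed cKO peak was the narrower one in 76 of 95 pairs (80.0%, 70.9 to 86.8), and the median width was 20.3 kb in control and 9.81 kb in Eed cKO. At other genes it was the narrower one in 380 of 774 pairs (49.1%, 45.6 to 52.6), with medians of 6.37 and 6.16 kb. These other genes are those outside the 5 lists, and they still include developmental factors such as Atoh1. In the widest of 10 equal classes of pairs the Eed cKO peak was the narrower one in 38 of 42 pairs (90.5%, 77.9 to 96.2) at the developmental factors and in 32 of 45 (71.1%, 56.6 to 82.3) at other genes. Counting all overlapped control peaks at genes, the median share covered by Eed cKO peaks was 61.5% for 142 peaks at the developmental factors and 90.7% for 898 others. These sets were not matched for control peak width, so no p is given.

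**Figure D4:**
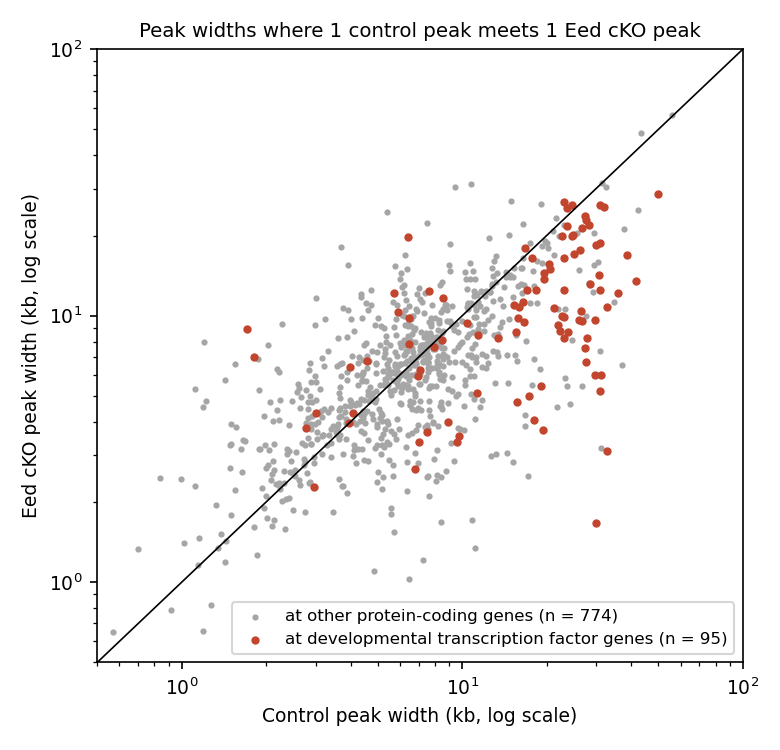
Widths (kb, log scales) of control and Eed cKO peaks at protein-coding genes where 1 control peak meets 1 Eed cKO peak; each point is a pair, the line marks equal widths, and there are no replicates. Of the 95 pairs at developmental transcription factor genes 76 lie below the line, against 380 of 774 at other genes.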

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

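The strata of peak width, the count of each control peak once and the other overlap rules for chromosomes were tests chosen only after the data were seen. No paired analysis was possible because each genotype had 1 peak list and no values per library, and for the same reason no replicate could be left out. CpG content and the CpG-dense background were not run without a genome sequence. The retention calls depended on the settings. The count of 5 lists became 1 with the wider peaks of each list, the trimmed control list, a window of 1000 bp, autosomes alone and control-marked genes with the wider peaks, and 0 within deciles of control peak width. The homeobox list outside the Hox clusters stayed past the threshold under all 8 settings fixed in advance. Merging of peaks, among these settings, left every retention odds ratio as it was, so it did not test the calls. With autosomes alone the adjusted p of the other 4 moved from 0.049 to between 0.057 and 0.068 while their odds ratios hardly moved (Hox 2.61 to 2.57, neuronal 2.79 to 2.75, mesodermal and endodermal 2.61 to 2.57, paired box to GATA 1.94 to 1.92), so these calls lay at the threshold. Within width deciles the odds ratio of paired box to GATA factors turned to 0.806. The count of genes marked in both lists, 1249, became 814 with the wider peaks of each list, which holds fewer peaks. The overlap of 37.9% became 47.2% with the trimmed control list and 32.5% when 50% of a peak had to be covered. The width difference of 842 bp became -1472 bp with the trimmed list, which keeps the widest control peaks by construction. Other causes were not tested. The number of lists enriched in control lay between 11 and 12 in 7 alternatives. Of 147 single-list alternatives 138 kept their call in control, and 146 of 147 in Eed cKO. These counts include lists that passed in no setting. Merging of peaks left every enrichment value as it was, and trimming the control list could not change an Eed cKO call. The counts therefore overstate how far the calls were tested. Unknown read depth limits every statement on peaks missing from a list.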

Other observations

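The width comparison of paired peaks, with its 3 tests, and the test of nesting for Eed cKO peaks were chosen only after the results were seen. The 5 developmental lists were also joined only after their retention calls were seen, and the 3 patterns weighed below were picked from seen results. Genes marked in Eed cKO alone included several developmental regulators. Among genes unmarked in control, 3 of 7 Hox genes (Hoxa4, Hoxb3 and Hoxc4; adjusted p = 0.0024) and 2 of 7 other homeobox genes (Dlx4 and Irx2; adjusted p = 0.038) had an Eed cKO peak, by Fisher's exact test over 21 lists. The peaks at Hoxb3 and Hoxc4 overlapped control peaks at the neighbouring Hoxb5 and Hoxc5, while those at Hoxa4, Dlx4 and Irx2 overlapped none. An Eed cKO peak also lay at 4 of 32 signalling ligands (Wnt4, Wnt7b, Wnt9b and Fgf11; adjusted p = 0.022, Fisher's exact test) and 7 of 124 channel and receptor genes (5.65%, adjusted p = 0.041). Of the 21 lists, 4 were higher and 2 lower. Housekeeping genes, a comparison list, had such a peak in 3 of 30 cases (10.0%), against 1.91% of other genes unmarked in control. That count did not pass the threshold (adjusted p = 0.058, Fisher's exact test), but its share was above that of the channel and receptor genes. Such peaks were thus not limited to developmental regulators. The widest such peaks lay at Fgfr3, a fibroblast growth factor receptor (38.6 kb on chromosome 5), Unc13a (27.0 kb), Tedc1 (19.7 kb), Phlda2 with Slc22a18 (17.0 kb), Irx2 (16.6 kb) and Foxn1, a hair and thymus factor (16.4 kb). Lgals2, Arhgef16 and Oaz1 followed, at 15.4, 15.3 and 15.0 kb. Of these wide Eed cKO peaks, each but the one at Irx2 overlapped a control peak away from the ends of the named gene.

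Some of the widest control domains marked a further gene alongside a developmental regulator. Ttll6 shared a 57.0 kb control peak with Hoxb13, Elp4 a 46.7 kb peak with Pax6, and Pcca a 42.4 kb peak with Zic2 and Zic5. Each of the 3 was marked in control alone while the Eed cKO list kept peaks at Hoxb13, Pax6 and Zic2. Cadps2 shared a 40.9 kb control peak with Fezf1 that no Eed cKO peak covered.

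Developmental transcription factor genes were marked in both lists more often than other control-marked genes, with an odds ratio of 2.99 in the lists joined for their calls, which is no test of the pattern. With each control peak counted once the odds ratio was 3.24 (2.35 to 4.46), which argues against genes sharing a peak as the cause. Per peak, however, any overlap with an Eed cKO peak counted, not only a peak at a gene end. The measure thus changed along with the unit, and peak sharing was not isolated. Gene density does not account for the pattern, with an odds ratio of 3.36 (2.45 to 4.61) over its deciles. Over deciles of control peak width the odds ratio was 1.29 (0.910 to 1.84), so wider control peaks at these genes may account for most of the difference. Whether width stands for more mark or for a greater chance of overlap was not tested.

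At the same genes the Eed cKO peak was narrower than the control peak, with an odds ratio of 4.15 (2.46 to 6.99) against pairs at other genes. Over deciles of the geometric mean of both widths the odds ratio was 2.69 (1.53 to 4.70). This argues against wide peaks narrowing at any gene as the only cause but cannot exclude it. Of the 95 developmental pairs, 42 lay in the widest class, within which widths were not matched. Pairs were also assigned to genes by the control peak alone. Whether a loss of sensitivity narrows peaks of every width cannot be told from the pairs: the Eed cKO peak was the narrower one in 47.0% (44.5 to 49.6) of all 1470, but control peaks that were lost or met several Eed cKO peaks are not among them. A loss of sensitivity at wide peaks stays open. In the widest of 10 equal classes of pairs, the Eed cKO peak was the narrower one in 71.1% (56.6 to 82.3) at other genes. The share was 90.5% (77.9 to 96.2) for the developmental pairs. These intervals overlap, which does not show that the shares are equal, and the shares were not tested against each other. Loss of weak flanks and of the mark itself were not tested apart, as peak heights were not used here.

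The 760 Eed cKO peaks without a control peak made up 29.9% (28.2 to 31.7) of that list. Whether a less sensitive Eed cKO list is the only difference cannot be told from this share, as no second list of a genotype shows how many peaks fall outside without a change. Calls scattered at random are argued against, since 37.9% lay at gene ends and at most 14.9% did in 1000 random placements. A bias toward gene-dense sequence remains possible: the median number of protein-coding genes within 250 kb was 7 at these peaks and 5 at control peaks without an Eed cKO peak, a difference of 2 (permutation p = 3e-05). Peaks shared by the lists had the same median of 7 (3 to 13), and with 1 list each a shift of the mark and a difference between libraries cannot be told apart.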
